A study of Mus musculus with 12 samples.

How the data were processed

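RNA was measured by bulk sequencing of polyA RNA from migratory DCs sorted from liver, duodenum and pancreas of B6 mice. Groups were the 3 tissues named in the sample titles, with 4 libraries each. The series design text states that each library pools 2 mice, so the libraries of 1 tissue are separate pools. The sort kept live CD45+ cells that were lineage-negative, CD11c+, MHC class II-high, CD103+ and CD11b-negative, per the labels' protocols. Single-cell data that the series design also mentions were not used here.

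Per the submitters' processing notes, the tool was kallisto, with no version given, and the genome build was GRCm39. The transcript index, the annotation release, the summary to genes and the strandedness are not given in the sources used here. The authors deposited 1 table of estimated counts and 1 table of TPM, a unit scaled for gene length and library size, both with 55401 genes in the 12 libraries. The ratio of deposited count to TPM split into 1 term per gene and 1 per library for the 12632 genes above 1 TPM in every library, with a largest deviation of 1.1e-09 on the log2 scale. That is the form of counts rebuilt from TPM with gene lengths averaged over libraries, and no label names such a step. Gene symbols came from the TPM table, and 110 genes shared a symbol with an earlier gene. No row lacked a gene identifier, 3 columns of the TPM table had no name and no values, and 0 columns of values lacked a sample. The reference annotation supplied here belongs to another mouse build, so no coordinates were used or printed.

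The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its minimum count of 10, which left 44624 genes. Libraries were scaled by TMM, and 1 model without an intercept or a block was fitted to all 12 libraries with a robust quasi-likelihood fit. Each pair of tissues was compared with the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene is from this test, and a standard error (SE) of a log2 difference is its absolute value over the square root of F. Normalised values are CPM, counts scaled to library size with TMM factors. A tissue-specific gene was called higher, or lower, in 1 tissue against both others. Overlaps between comparisons that share a tissue were set beside 20 simulated draws of unchanged groups, beside the overlap of independent lists, and beside 6 splits of the shared libraries into pairs.

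Gene lists were written from general knowledge of DCs, of stress and metabolic pathways, and of other cell types, most of which the gate excludes. They were 32 lists with 661 symbols, of which 657 were tested. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over 96 tests. For each list, counts of called members are given over all genes tested and adjusted over the list alone. The lists were for cDC1 identity, cDC2 markers, DC maturation and migration, the retinoic acid pathway, TGF-beta and regulatory genes, interferon response, MHC class II and class I presentation, inflammatory cytokines and chemokines, trafficking receptors, pattern recognition, immediate-early and heat-shock genes, cholesterol synthesis, LXR and lipid handling, glycolysis and hypoxia, AHR targets and cell cycle. Lists for other cells covered hepatocytes, pancreatic acinar and islet cells, intestinal epithelium, B cells, plasma cells, T cells, NK cells and ILCs, macrophages and Kupffer cells, monocytes, neutrophils, plasmacytoid DCs, endothelium, stroma and erythroid cells. The summed CPM of each list was also computed per library. The preset correlation is liberal here, since 29 other groupings of the 12 libraries called 7 to 44 lists, so list calls are given with the adjusted p at an estimated correlation, with which 11 of 51 calls held.

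The distance of pancreas to the other tissues used log2 CPM with a prior count of 2 over the 1000 genes of highest variance. The mean Euclidean distance of pancreas libraries to liver libraries minus that to duodenum libraries was tested with an exact two-sided permutation test of the 8 liver and duodenum labels.

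The genes named follow a rule. It took, per comparison and direction, the 8 called genes with the largest log2 difference among those with a mean of at least 10 CPM in the higher tissue and no overlap between the 4 libraries of each tissue. Predicted genes, antigen receptor segments and members of lists for other cells were left out of that part. It also took up to 3 called members per list, and the sort markers and cDC1 genes whatever they showed. Under the limits of the first part, it took 5 tissue-specific genes per tissue and direction. Outside the rule, Cd200, Rxra, Calr, Pdia3, Pacsin1, Scd2, Srebf1, Jchain, Cd79a, Mzb1 and Ighg3 were each chosen after its values were seen. Values of gene families with near-identical members (Mup, Serpina1, Amy2a, Pilrb, Apol, Ly6, H2-Q, Klra and immunoglobulin genes) are uncertain, because the counting could split their reads.

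The tests of the comparisons, the gene lists, the naming rule and the alternatives other than 4 settings were fixed before the data were examined. Most tests of technical explanations were chosen later and are named where they are given. Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(TPM + 1) with other pseudocounts and filters, other scalings and filters of the counts, a replicate block, stricter thresholds, fits to the 8 libraries of a pair, removal of genes of other cell types, and each library left out in turn. The 4 settings added after the data were seen removed antigen receptor and acinar genes, removed ribosomal and repeat features, left out the 3 liver and pancreas libraries with immunoglobulin reads, or left out duodenum 2 and pancreas 1. Without the 3 libraries only liver 1, 3 and 4 and pancreas 1 and 2 stayed in those tissues. A call that ended there may have ended from lost power alone.

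The fit was tested on simulated counts with 200 changed genes per comparison, drawn from the means and sizes of these libraries. The changed genes were picked among those with a mean of at least 1 CPM, so recovery in rarer genes was not measured. At a 2-fold change it recovered 38%, 35% and 40% of 100 changed genes for liver versus duodenum, pancreas versus duodenum and liver versus pancreas. At a 4-fold change it recovered 94%, 91% and 96%. Of the genes called there, 3.65%, 3.82% and 5.56% were unchanged. Each library held 220.9 to 356.1 M (mega) estimated counts, and shares of counts in single libraries carry exact Clopper-Pearson 95% intervals, which cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.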

Results

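Migratory DCs, which carry antigen from tissues to lymph nodes, were compared between liver, duodenum and pancreas, 3 organs whose lymph reaches shared nodes. The cells were sorted by the surface profile of conventional type 1 DCs (cDC1) from B6 mice of 6 to 8 weeks. Each tissue gave 4 libraries, each from a pool of 2 mice. The 12 libraries held 273 ± 36.6 M (mega) estimated counts (SD, n = 12), with totals from 220.9 to 356.1 M. Mean totals were 272 ± 40.4 M in liver, 284 ± 53.4 M in duodenum and 262 ± 10.4 M in pancreas (SD, n = 4 each). The most abundant feature, CT010467.1, took 9.03 ± 1.27% of counts (SD, n = 12). Correlations of log2 CPM across genes ran from 0.944 to 0.959 within a tissue and from 0.931 to 0.953 between tissues. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom ran from 81.2 to 435 over the 18 pairs within tissues.

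Libraries of the 3 tissues separated on the first principal components. In the 1000 most variable genes, the first component took 31.1% of the variance and set duodenum apart from liver and pancreas, and the next took 17%.

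**Figure D1:**
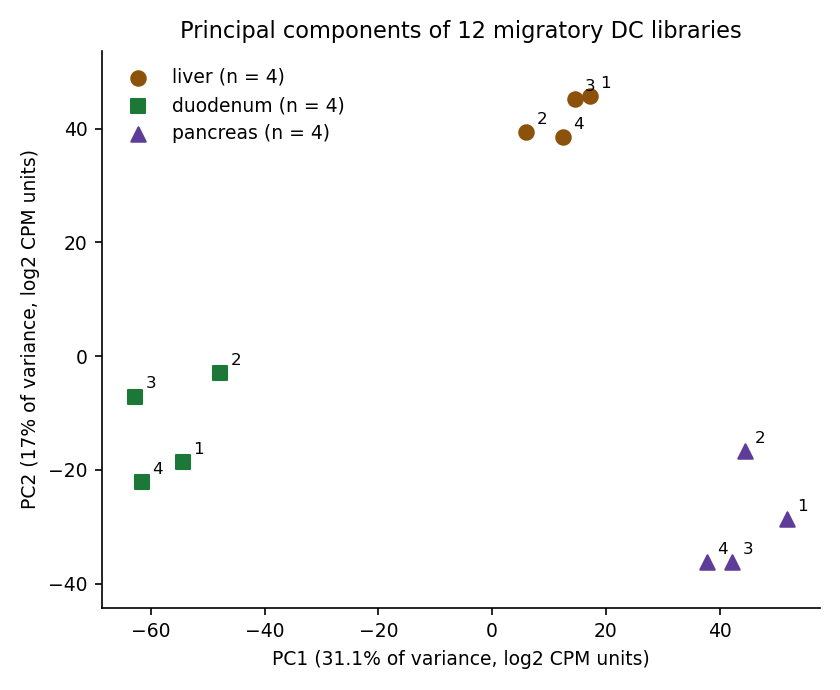
Each point is 1 library, placed by its scores on the first and next principal component of log2 CPM over the 1000 genes of highest variance, with its replicate number beside it. The 4 duodenum libraries lie at scores of -62.77 to -47.77 on the first component, liver at 6.043 to 17.22 and pancreas at 37.77 to 51.89.

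The genes that define cDC1 were expressed in every tissue. Xcr1, the chemokine receptor by which cDC1 meet T cells, stood at 611 ± 77.5 CPM in liver, 535 ± 149 in duodenum and 406 ± 49.5 in pancreas (SD, n = 4 each). Clec9a, a receptor for dead cells, and Irf8 and Batf3, transcription factors that cDC1 need to develop, did not pass the test in any comparison with all libraries, nor did Xcr1. The lowest adjusted p of these 4 genes was 0.09, for Batf3 between pancreas and duodenum (edgeR quasi-likelihood test). Of 32 alternatives, 9 called Batf3 lower in pancreas than in duodenum, and 3 each Xcr1 and Irf8. In liver 4 called Clec9a higher and 2 called Irf8 lower than in duodenum, and 8 called Xcr1 higher than in pancreas. Without duodenum 2, Irf8 was called in liver and pancreas against duodenum (adjusted p = 0.00833 in pancreas). Xcr1 was then called in pancreas against duodenum (adjusted p = 0.00438) and against liver. Without pancreas 3, Batf3 was called against duodenum (adjusted p = 0.0113). H2-Ab1, an MHC class II gene, was at 17600 ± 1460, 18570 ± 3100 and 17720 ± 2030 CPM in liver, duodenum and pancreas. Itgam, which encodes the excluded marker CD11b, was at 1.70 ± 1.15, 2.46 ± 0.65 and 2.67 ± 0.95 CPM. Of the other sort markers, Itgae (CD103) was lower than in duodenum by a log2 difference of -0.81 ± 0.17 in liver (SE, adjusted p = 0.00704) and -0.77 ± 0.17 in pancreas (adjusted p = 0.00899). Itgax (CD11c) was lower in pancreas than in duodenum (-0.89 ± 0.16, adjusted p = 0.00293), and Ptprc (CD45) was called in no comparison with all libraries but lower in liver and pancreas than in duodenum without duodenum 2 (adjusted p = 0.0171 and 0.00627).

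In the cDC1 identity list of 18 tested genes, Cd207 and Gcsam were higher in liver and in pancreas than in duodenum, and Cd8a was lower. Langerin, the product of Cd207, is a lectin of skin and mucosal DCs. Cd207 was at 32.8 ± 6.03 CPM in liver, 0.36 ± 0.43 in duodenum and 65.1 ± 14.5 in pancreas (SD, n = 4 each). Against duodenum, 4 members were higher and 2 lower in liver (8 and 2 adjusted over the list alone), with a camera adjusted p = 0.00359, and adjusted p = 0.581 with an estimated correlation. In pancreas 5 were higher and 4 lower (6 and 5 adjusted over the list alone), and the list test did not pass (adjusted p = 0.669). Between liver and pancreas 2 were higher in liver, Cd8a and Snx22 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000575), with adjusted p = 0.546 with an estimated correlation. Among 15 genes of MHC class II presentation, Cd63 and Lgmn were higher in both liver and pancreas than in duodenum, and 2 were lower in pancreas, with Ciita at -0.67 ± 0.11 (3 and 0 adjusted over the list alone in liver, 3 and 2 in pancreas). Ciita was also the 1 member higher in liver than in pancreas (1 adjusted over the list alone), and that call ended when any of 8 single libraries, or the 3 with immunoglobulin reads, were left out. The call of Lgmn in pancreas against duodenum ended when any of 7 was. The MHC class II list passed in no comparison (lowest camera adjusted p = 0.317).

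Transcripts of other cell types were present in the sorted libraries. The 28 acinar genes, which encode digestive enzymes, summed to 4050 ± 2500 CPM in pancreas, 9.24 ± 1.05 in liver and 15.9 ± 8.2 in duodenum (SD, n = 4 each). Plasma cell genes summed to 10200 ± 2070 CPM in duodenum, 132 ± 251 in liver and 321 ± 359 in pancreas. Within those groups liver 2, pancreas 3 and pancreas 4 stood at 508.5, 607.6 and 654 CPM and the other 5 libraries between 5.921 and 12.54 CPM. The hepatocyte list summed to 131 ± 15.4 CPM in liver, 24.1 ± 6.72 in duodenum and 146 ± 39.1 in pancreas, where Ass1, an enzyme of arginine synthesis that many cells express, alone made up 139 ± 40.3 CPM. The intestinal epithelium list was not highest in duodenum, at 203 ± 12.9 CPM there, 113 ± 5.39 in liver and 252 ± 32.5 in pancreas. Zg16 alone made up 66.4 CPM of the pancreas sum, more than the gap between pancreas and duodenum. Over the pancreas libraries Zg16 rose with the acinar sum (slope 0.966 on the log2 scale).

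**Figure D2:**
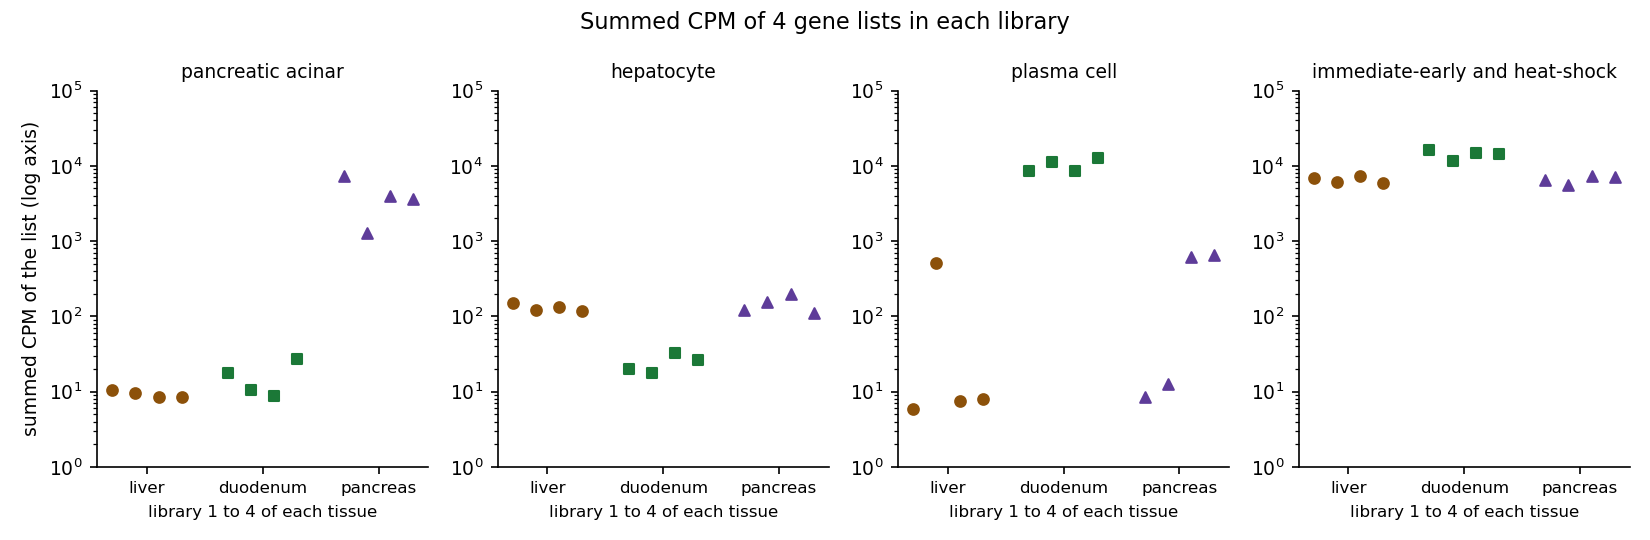
Each point is the summed CPM of a gene list in 1 library, on a log axis, for the 4 libraries of each tissue from left to right. Acinar sums lie between 1283 and 7354 CPM in pancreas and at 26.74 CPM or less elsewhere, and the immediate-early and heat-shock sums lie between 11720 and 16110 CPM in duodenum and at 7419 CPM or less elsewhere.

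The comparison of liver with duodenum asked how cells of 1 sort differ between organs that share draining nodes. DCs from liver held more transcripts of maturation and migration genes. Ccr7, the chemokine receptor that guides DCs to lymph nodes, was at 220 ± 64.5 CPM in liver and 19.1 ± 11.1 CPM in duodenum (SD, n = 4 each), a log2 difference of 3.53 ± 0.43 (SE, adjusted p = 0.000125, edgeR). Ccl5, a chemokine for T cells, was at 139 ± 58.2 against 1.64 ± 1.83 CPM, and Il12b, a cytokine gene of T cell priming, at 50.2 ± 15.4 against 3.34 ± 1.07 CPM. Il15ra, which presents the cytokine IL15 to lymphocytes, differed by 3.63 ± 0.36. Of the 31 genes tested, 19 were higher and 1, Cd200, was lower in liver until any of 3 single libraries was left out (21 and 1 adjusted over the list alone). The list's camera adjusted p was 6.02e-26, and adjusted p = 0.0708 with an estimated correlation.

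Immediate-early and heat-shock genes, which respond quickly to stimulation and to cell handling, were lower in liver. Fos was at 60.5 ± 6.11 CPM in liver and 1057 ± 210 CPM in duodenum, Egr1 at 12.4 ± 3.35 and 279 ± 45.9 CPM, and Fosb at 11 ± 1.52 and 226 ± 26.3 CPM (SD, n = 4 each). Of 32 genes 25 were lower and 0 higher (25 and 0 adjusted over the list alone, camera adjusted p = 3.49e-74), and the call held with an estimated correlation (adjusted p = 0.000403). Nr4a2, a nuclear receptor of the same early response, was at 3.77 ± 1.19 against 97.5 ± 31 CPM. Mitochondrial genes took 1.33 to 1.42% of the counts in duodenum and 1.12 to 1.24% in liver, and their protein-coding members 0.722 to 0.885% and 0.575 to 0.656%.

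Some genes of retinoic acid metabolism were higher in duodenum than in liver. Aldh1a2, which makes retinoic acid, was at 7.38 ± 3.36 CPM in liver and 76.6 ± 13.2 in duodenum, and Cyp26b1, which degrades it, at 1.41 ± 1.15 and 73.2 ± 21.9 CPM (SD, n = 4 each). In this list of 20 genes, 5 were lower in liver, among them the receptor gene Rarb (-2.63 ± 0.31), and 1, Rxra, was higher until any of 11 single libraries was left out (6 and 1 adjusted over the list alone). Its camera adjusted p was 0.000391 and held with an estimated correlation (adjusted p = 0.0209), while its median log2 difference of 0.02 had the opposite sign to its mean of -0.59. Cholesterol synthesis genes were lower in liver for 17 of 24 members and higher for 0 (20 and 1 adjusted over the list alone, camera adjusted p = 1.23e-18), with adjusted p = 0.0614 with an estimated correlation. Fdps, of the mevalonate pathway, differed by -1.60 ± 0.25 and Sqle, of sterol synthesis, by -1.41 ± 0.24.

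Interferon response genes were higher in liver for 10 of 33 members, such as Mx1 (2.37 ± 0.16) and Iigp1 (2.64 ± 0.33), and lower for 0 (18 and 1 adjusted over the list alone, camera adjusted p = 1.63e-10). That list had adjusted p = 0.182 with an estimated correlation. Replication genes such as Pcna (-1.27 ± 0.16) and Mcm3 (-1.22 ± 0.16) were among the 11 of 32 cell cycle genes lower in liver, and 0 were higher (20 and 0 adjusted over the list alone, camera adjusted p = 4.02e-13, and adjusted p = 0.207 with an estimated correlation). Of 26 trafficking receptors 6 were higher, such as the integrin gene Itgal (3.66 ± 0.17) and the chemokine receptor gene Ccr2 (3.23 ± 0.21), and 4 lower, such as Ccr1 (-5.17 ± 0.56) and Ccr9 (-1.25 ± 0.28). The trafficking counts were 7 and 5 adjusted over the list alone, with a camera adjusted p = 0.00994, and adjusted p = 0.273 with an estimated correlation. Among 14 markers of the other conventional DC type, cDC2, 7 were lower in liver, such as Cd209d (-5.09 ± 0.79) and Mgl2 (-1.93 ± 0.42), with Ccr2 the 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 3.93e-05, and adjusted p = 0.0659 with an estimated correlation). Their summed CPM went the other way, with 543 ± 19.9 in liver, of which Ccr2 made up 390 ± 20.8, and 242 ± 50.6 in duodenum, with Ccr2 at 41.7 ± 13.3 (SD, n = 4 each).

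Id3 (ENSMUSG00000007872), an inhibitor of transcription factor binding, was at 143 ± 12.1 CPM in liver and 0.62 ± 0.31 in duodenum. Liver was also higher for Serpinf1 (5.59 ± 0.37), which encodes a secreted serpin, and for Cyp8b1 (4.77 ± 0.30), a sterol hydroxylase. Mup22, Mup7 and Serpina1e, which belong to families of proteins secreted by hepatocytes, were at 12.7 ± 2.84, 19.5 ± 4.01 and 14.2 ± 7.88 CPM in liver and at 0.03 ± 0.05, 0.30 ± 0.15 and 0.15 ± 0.05 CPM in duodenum. Beside them 22 of 25 hepatocyte genes were higher in liver and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 6.64e-44, and adjusted p = 0.000403 with an estimated correlation). Duodenum was higher for the paired receptor genes Pilrb1 and Pilrb2 (-5.93 ± 0.67 and -5.55 ± 0.83), for Cpm, a membrane peptidase (-4.36 ± 0.24), and for Il22ra2, a decoy receptor for the cytokine IL22 (-4.33 ± 1.17, adjusted p = 0.0475). Leaving out any of 8 single libraries ended the call of Il22ra2. Plasma cell genes were lower in liver for 11 of 13 members and higher for 0 (12 and 0 adjusted over the list alone, camera adjusted p = 8.29e-33, and adjusted p = 0.000403 with an estimated correlation), with Igha at 0.17 ± 0.08 against 5538 ± 1060 CPM. Acinar genes were called in 0 of 28 cases (0 adjusted over the list alone), although the list test passed (camera adjusted p = 0.0168, median log2 difference -0.49, and adjusted p = 0.62 with an estimated correlation).

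In all, 3265 of 44624 genes were called between liver and duodenum, 1502 higher in liver and 1763 higher in duodenum (edgeR quasi-likelihood test, adjusted p under 0.05). The share higher in liver was 46%, and was 35.3% with DESeq2 size factors (1078 and 1976 genes), 63.5% with library totals (2642 and 1520) and 63.3% with limma on TPM (3053 and 1769), with medians over all genes of 0.10, 0.02, 0.25 and 0.14 on the log2 scale. Without the 3 libraries with immunoglobulin reads the count was 2069 and the calls of Lgmn, Cd200 and Rxra ended, and without duodenum 2 and pancreas 1 it was 4913. Without duodenum 2 alone 1539 genes were higher in liver and 3268 in duodenum (32%), and without liver 1, 2 or 3 those higher in liver were 970, 969 or 990.

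Pancreas and duodenum, neighbouring organs, were compared in the same way. DCs from pancreas also held more transcripts of maturation genes than those from duodenum, with Ccr7 at 240 ± 107 CPM, Ccl5 at 350 ± 175 CPM and Il12b at 72.4 ± 27.4 CPM in pancreas (SD, n = 4 each). The log2 differences were 3.65 ± 0.43, 7.75 ± 1.08 and 4.44 ± 0.35 (SE, adjusted p = 7.37e-05, 0.00116 and 1.62e-06, edgeR). Of 31 maturation genes 21 were higher and 1, Cd274, was lower (22 and 2 adjusted over the list alone, camera adjusted p = 1.89e-26, and adjusted p = 0.0743 with an estimated correlation). Cd207 was higher by 7.52 ± 1.03, and Ltb4r1, a leukotriene receptor, was at 32.8 ± 2.05 CPM in pancreas and 0.49 ± 0.26 in duodenum.

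Several genes were low in pancreas and abundant in duodenum. Apol7c, of the apolipoprotein L family, was at 24.5 ± 20.6 CPM in pancreas and 2434 ± 358 in duodenum, and Apol10b at 1.27 ± 0.86 and 94.7 ± 21.5 CPM (SD, n = 4 each). Hic1, a transcriptional repressor, was at 3.70 ± 3.38 and 292 ± 58.2 CPM, and Dapk2, a calmodulin-dependent kinase, at 1.52 ± 0.25 and 112 ± 11.1 CPM. Ffar2, a receptor for short-chain fatty acids, was at 0.74 ± 0.55 and 25 ± 5.51 CPM. Cyp26b1, Pilrb1 and Pilra were lower in pancreas by -6.04 ± 0.59, -5.68 ± 0.66 and -5.13 ± 0.33.

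Cholesterol synthesis genes were lower in pancreas for 19 of 24 members and higher for 0 (21 and 0 adjusted over the list alone, camera adjusted p = 8.38e-35), which held with an estimated correlation (adjusted p = 0.00854). Fdps was at 51.1 ± 22.6 CPM in pancreas and 285 ± 24.3 in duodenum, and Sqle, of sterol synthesis, differed by -2.17 ± 0.25. Immediate-early and heat-shock genes were lower for 20 of 32 members and higher for 0 (23 and 0 adjusted over the list alone, camera adjusted p = 3.67e-41, and adjusted p = 0.0021 with an estimated correlation), with Fosb at -3.17 ± 0.38 and Fos at -2.95 ± 0.21. Mitochondrial genes took 1.09 to 1.19% of the counts in pancreas, against 1.33 to 1.42% in duodenum, and their protein-coding members 0.629 to 0.711%. In the retinoic acid list 4 genes were lower, such as Aldh1a2 (-2.71 ± 0.34) and Ncoa7 (-1.60 ± 0.21), and 2 higher, Dhrs3 (0.88 ± 0.18) and Rxra (0.66 ± 0.19), the last until any of the 12 single libraries was left out. That list had 5 and 4 adjusted over the list alone, a median of 0.08 against a mean of -0.34, a camera adjusted p = 0.0457, and adjusted p = 0.124 with an estimated correlation.

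Trafficking receptors were higher in pancreas for 9 of 26 members, with Itgal at 3.45 ± 0.16 and Ccr2 at 3.44 ± 0.21, and lower for 4, with Ccr9, a gut-homing receptor, at -2.72 ± 0.29 (9 and 4 adjusted over the list alone, camera adjusted p = 0.000142, and adjusted p = 0.124 with an estimated correlation). Among 33 interferon response genes 5 were higher, including Mx1 (2.05 ± 0.16), and 3 lower, including the chemokine genes Cxcl9 (-2.44 ± 0.30) and Cxcl10 (-2.91 ± 0.52), and the list test did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.0608). Only Pcna of 32 cell cycle genes was called, lower in pancreas (1 adjusted over the list alone, camera adjusted p = 0.908). Of 14 cDC2 markers 7 were lower, such as Cd209d (-4.88 ± 0.78), and 1, Ccr2, higher (7 and 3 adjusted over the list alone, camera adjusted p = 0.0271, and adjusted p = 0.261 with an estimated correlation). Their sum was higher in pancreas, at 640 ± 66.9 CPM, with Ccr2 at 453 ± 62.5 (SD, n = 4).

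Digestive enzyme genes were higher in pancreas. Pla2g1b, a pancreatic phospholipase, was at 29 ± 12.8 CPM in pancreas and 0.05 ± 0.03 in duodenum, and 24 of 28 acinar genes were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 3.03e-87, and adjusted p = 0.00327 with an estimated correlation). Amy2a2, Amy2a3 and Amy2a4, amylase genes with identical values in every library, were each at 255 ± 144 against 0.78 ± 0.44 CPM. Plasma cell genes were lower for 10 of 13 members and higher for 0 (11 and 0 adjusted over the list alone, camera adjusted p = 3.57e-23, and adjusted p = 0.000681 with an estimated correlation). From the hepatocyte list only Ass1 was called, higher in pancreas by 2.98 ± 0.28 (1 adjusted over the list alone, camera adjusted p = 0.16).

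In all, 3437 genes were called between pancreas and duodenum, 1680 higher in pancreas and 1757 higher in duodenum (edgeR quasi-likelihood test). The share higher in pancreas was 48.9%, and was 40% with DESeq2 size factors (1294 and 1943 genes), 56.8% with library totals (2354 and 1790) and 35.7% without duodenum 2 (1682 and 3034). Without the 3 libraries with immunoglobulin reads the count was 1712 and the calls of Itgae, Lgmn and Rxra ended.

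**Figure D3:**
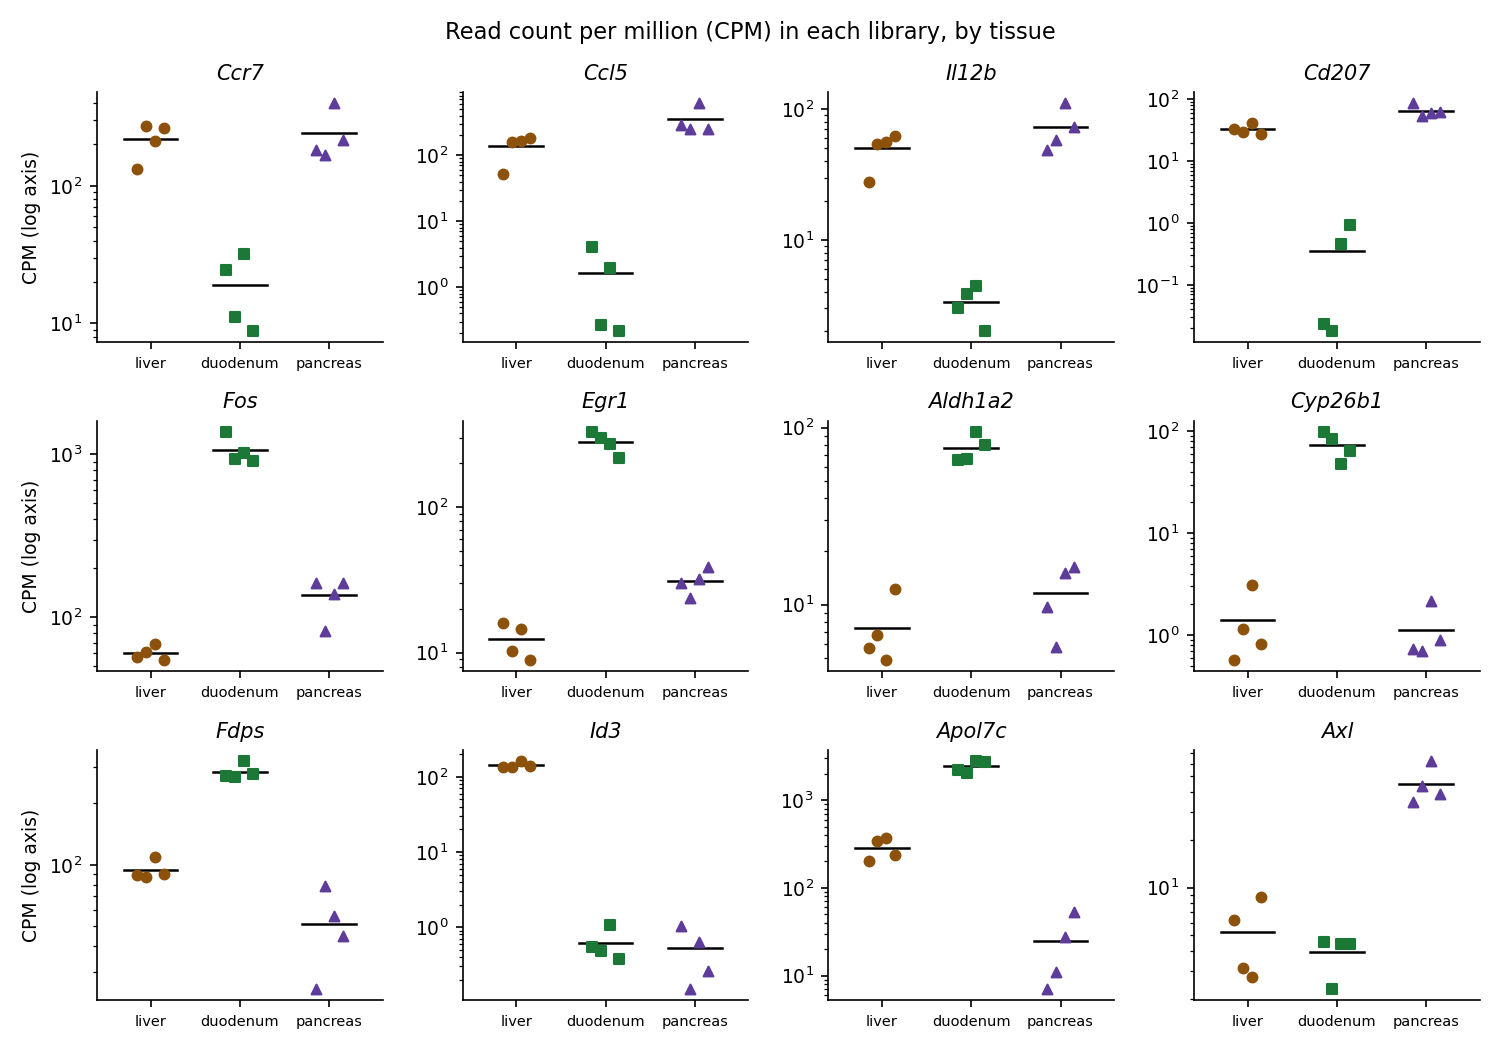
Each point is the CPM of a gene in 1 library on a log axis, and each bar is the mean of the 4 libraries of a tissue. Ccr7, Ccl5, Il12b and Cd207 are lowest in the 4 duodenum libraries, Fos, Egr1, Aldh1a2, Cyp26b1, Fdps and Apol7c are highest there, Id3 is at 143 CPM on average in liver and at 1.07 CPM or less in each library of the other tissues, and Axl is highest in pancreas.

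Fewer genes separated liver from pancreas. Id3 was at 143 ± 12.1 CPM in liver and 0.52 ± 0.40 in pancreas (SD, n = 4 each), a log2 difference of 8.09 ± 0.59 (SE, adjusted p = 3.12e-06, edgeR). Ly6a, a surface antigen that interferon induces, was at 82.2 ± 8.3 and 6.59 ± 2.49 CPM, and Apol7c at 287 ± 81.3 and 24.5 ± 20.6 CPM. Liver was also higher for Plac8 (3.09 ± 0.29), the co-receptor gene Cd8a (2.36 ± 0.23), Tlr12 (2.03 ± 0.21), a sensor of parasite profilin, and Apoe (2.55 ± 0.30), a lipid carrier. Ctla2b, of a family of protease inhibitors, was at 119 ± 13.1 and 16.3 ± 3.43 CPM.

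Pancreas was higher than liver for Axl, a receptor kinase that binds dying cells, at 44.9 ± 12.1 against 5.24 ± 2.85 CPM (log2 difference -3.10 ± 0.37, adjusted p = 0.000352). Ltb4r1 (-3.40 ± 0.37), Pdlim1, a cytoskeletal adaptor (-4.27 ± 0.26), Spp1, which encodes osteopontin (-2.72 ± 0.29), Cass4 (-3.13 ± 0.40) and the chemokine gene Ccl9 (-1.84 ± 0.20) were higher too, although the call of Cass4 ended without the 3 libraries with immunoglobulin reads. Nupr1, Tff2 and Gp2, genes expressed by exocrine pancreas, were at 37.1 ± 20.3, 15.5 ± 8.5 and 10.7 ± 7.46 CPM in pancreas and 1.26 ± 0.47, 0.06 ± 0.04 and 0.16 ± 0.06 CPM in liver, beside 25 of 28 acinar genes higher in pancreas and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 4.52e-207, and adjusted p = 0.000336 with an estimated correlation). Hepatocyte genes were higher in liver for 18 of 25 members, with Ass1 the 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 7.75e-68, and adjusted p = 0.000296 with an estimated correlation).

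Maturation genes differed little between liver and pancreas: 2 of 31 were higher in liver, Pdcd1lg2 (2.21 ± 0.34) and Cd274 (1.54 ± 0.34), both ligands of the inhibitory receptor PD1, and 0 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.304). The call of Cd274 (adjusted p = 0.0445) ended when any of 9 single libraries was left out. Both calls ended without the 3 libraries with immunoglobulin reads (adjusted p = 0.135 for Pdcd1lg2), where lost power alone may end calls. Immediate-early and heat-shock genes were lower in liver for 7 of 32 members, such as Fos (-1.18 ± 0.20) and Nr4a1 (-2.06 ± 0.24), and higher for 0 (13 and 1 adjusted over the list alone, camera adjusted p = 6.34e-13, and adjusted p = 0.0659 with an estimated correlation). Cell cycle genes were lower in liver for 4 of 32 members, such as Rrm2 (-1.07 ± 0.21) and Bub1b (-1.03 ± 0.20), and higher for 0 (24 and 0 adjusted over the list alone, camera adjusted p = 6.02e-24, and adjusted p = 0.102 with an estimated correlation). Leaving out any of 6 single libraries ended the calls of Rrm2 and of Bub1b, as did leaving out the 3 libraries. Interferon response genes were higher in liver for 4 of 33 members, such as Iigp1 (2.03 ± 0.32) and Cxcl9 (1.93 ± 0.29), and lower for 0 (5 and 0 adjusted over the list alone, camera adjusted p = 5.44e-10, and adjusted p = 0.191 with an estimated correlation).

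Of the remaining lists, cholesterol synthesis had 1 of 24 members higher in liver, Fdft1 (0.74 ± 0.17, adjusted p = 0.048), and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 8.28e-09, and adjusted p = 0.148 with an estimated correlation). The call of Fdft1 ended when any of 10 single libraries was left out. In the retinoic acid list 1 gene was lower in liver, Dhrs3 (-0.99 ± 0.18), a call that ended without liver 4, and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.0417, and adjusted p = 0.124 with an estimated correlation). Trafficking receptors had 1 higher, Ccr9 (1.47 ± 0.28), and 3 lower, including Gpr183 (-1.40 ± 0.22), an oxysterol receptor, and the list did not pass (2 and 4 adjusted over the list alone, camera adjusted p = 0.0639). The call of Ccr9 ended when any of 6 single libraries was left out, and without the 3 libraries with immunoglobulin reads those of Gpr183, Mgl2, Igha, Fdft1 and Dhrs3 ended. Among cDC2 markers only Mgl2 was called, lower in liver by -2.23 ± 0.42 (0 and 3 adjusted over the list alone, camera adjusted p = 0.0271, and adjusted p = 0.261 with an estimated correlation), and that call ended without liver 2 or liver 4. Plasma cell genes had 1 member lower in liver, Igha (-3.93 ± 0.73), whose call ended when any of 7 single libraries was left out (0 and 3 adjusted over the list alone, camera adjusted p = 0.000272, and adjusted p = 0.11 with an estimated correlation). Igha stood at 4.679 and 4.232 CPM in pancreas 2 and 4, and at 1.151 CPM or less in the other pancreas libraries.

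In all, 494 genes were called between liver and pancreas, 190 higher in liver and 304 higher in pancreas (edgeR quasi-likelihood test). The share higher in liver was 38.5%, and was 52.2% with library totals (428 and 392 genes) and 57.7% with limma on TPM (560 and 411). The count was 749 without duodenum 2 (295 higher in liver and 454 in pancreas) and 177 without the 3 libraries with immunoglobulin reads, and 198 genes were higher in pancreas without liver 4. Leaving out any 1 liver or pancreas library already took it to between 343 and 394. With genes of the lists for other cell types removed it was 413 (158 higher in liver and 255 in pancreas). Genes of such cells outside the lists, such as the amylase gene Amy2a1, stayed in that fit.

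Genes that set 1 tissue apart from both others were counted from the same tests. Duodenum had 1094 genes higher and 929 lower than in both other tissues, pancreas 177 and 101, and liver 77 and 92. These counts include members of lists for other cells, with 24 acinar genes among the 177 higher in pancreas. Under the naming rule, which leaves out members of lists for other cells, Cyp26b1, Pilrb1, Pilrb2, Pilra and Hic1 led those higher in duodenum. Cd207, Ccl5, Serpinf1, Cyp8b1 and Il12b led those lower there. Id3 and Ly6a were higher in liver, beside Mup22, Mup7 and Serpina1e of hepatocyte families, and Cass4, Pdlim1, Spp1, Egr2 and Il1b were lower there. The calls of Egr2 and Il1b against pancreas ended when any of 8 and 6 single libraries was left out, and without the 3 libraries with immunoglobulin reads. In pancreas the genes that led those higher were amylase genes and Pla2g1b, digestive enzyme genes that the acinar list did not hold. Apol7c, Apol10b, Ctla2b, Cd8a and Fndc5, which encodes the precursor of irisin, were lower there.

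Comparisons that share a tissue also share its chance values. For liver and pancreas against duodenum, log2 differences over 44624 genes correlated at r = 0.684, where simulated unchanged groups gave 0.499, and their covariance was 0.572 against 0.205, a difference of 0.367. The simulated groups shared 0 calls in 20 draws, but groups without any change give almost no calls, so that count sets no scale for the overlap. Independent lists of the observed sizes would share 69.4 higher and 56.5 lower calls against the 1094 and 929 observed. With the duodenum libraries split into pairs in 6 ways, r ran from 0.186 to 0.224 and the overlaps from 574 to 728 higher and 359 to 427 lower genes. Each comparison there used fewer libraries of the shared tissue, so lost power may also lower the overlaps from splits, here and below. For pancreas r was 0.452, below the simulated 0.501, while the covariance was 0.309 against 0.206 simulated, independent lists would share 11.4 and 7.48 genes, and split libraries gave 92 to 116 and 39 to 58 genes. For liver r was 0.341, below the simulated 0.499, and the covariance was 0.221 against 0.205 simulated, with 6.4 and 12 genes from independent lists and 33 to 39 and 17 to 25 genes from split libraries. Without duodenum 2 the counts were 2163 higher in duodenum, 175 lower in liver and 175 lower in pancreas, and without pancreas 1 the last was 59. Leaving out liver 1, 2, 3 or 4 or pancreas 3 took the 92 genes lower in liver to 59, 57, 58, 61 or 60.

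Whether pancreatic DCs resemble those of liver or of duodenum more was tested on whole profiles. The mean distance of pancreas libraries was 107.3 to liver and 130.6 to duodenum in log2 CPM over 1000 genes, a difference of -23.26 (exact permutation test, two-sided, p = 0.0286, the smallest that 70 labelings allow). Distances within a tissue averaged 81.7 in liver, 86.8 in pancreas and 100 in duodenum, and liver and duodenum were 119 apart. With antigen receptor and acinar genes removed, a setting chosen after the data were seen, the difference was -14.08.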

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

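The tests of both sources of immunoglobulin reads, of acinar RNA, of the share of DCs, of the scaling and of stress were chosen only after the result was seen. A library is given here when its gap to the nearest of the other 3 libraries of its tissue exceeded the share of the group's range that Dixon's test allows at 95%, which chance gives in about 1 of 20 groups. Of 480 groups of 4 libraries 40 did so, where chance would give 24.

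Immunoglobulin reads set apart 3 of the 8 liver and pancreas libraries. Antigen receptor genes took 0.121% of the counts of liver 2 (95% exact Clopper-Pearson interval 0.1206 to 0.1213), against 0.0172 to 0.0177% in the other liver libraries, and 0.1033% (0.103 to 0.1037) and 0.1257% (0.1253 to 0.1261) of pancreas 3 and 4, and plasma cell genes summed to 508.5 CPM in liver 2 against 5.921 to 8.085. Reads carried over from duodenum are argued against as the main source in these 3 libraries, since the ratio of Igha to Jchain was at most 0.0292 in them and at least 3.12 in duodenum. The ratio cannot exclude a small carry-over beside another source of Jchain, and pancreas 4 held 4.232 CPM of Igha. Plasma cells or their RNA may be the source, although the gate was lineage-negative: of 19 B and plasma cell genes other than Jchain and antigen receptor genes, 2 (Cd79a and Mzb1) were higher in all 3 libraries than in each of the other 5, and 4 of 56 splits of the 8 libraries gave as many, up to 3 genes (exact permutation p = 0.0714), so this source stays open. Jchain stood at 72.5 to 145 CPM against at most 1.97 in the other 5, Cd79a at 2.26 to 2.47 against at most 0.267 and Ighg3 at 246 CPM in liver 2. Ighm was at 332.5 and 348.4 CPM in pancreas 3 and 4 and at 134 in liver 2, against 124.7 to 151.9 in the other 5. Pancreas 2, outside the 3 libraries, held 4.679 CPM of Igha at a ratio to Jchain of 4.04, as in duodenum, so carry-over remains open for that library.

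Genes higher in pancreas than in both other tissues could come from RNA of acinar or stromal cells, which the gate (CD45+, CD11c+, MHC class II-high) should exclude as cells though not as free RNA, and which bring all their transcripts together. Over the 4 pancreas libraries the acinar sum ranged 5.73-fold. The 24 acinar genes had a median slope of 1.05 on it, but they are part of that sum, so such a slope is largely built in. Nupr1, Tff2 and Gp2, exocrine pancreas genes outside the list, had slopes of 0.691, 0.727 and 1.363. The 153 genes outside the list had a median slope of -0.044 (interquartile range -0.134 to 0.099), which argues against acinar RNA for most of them. Of those, 17 had slopes over 0.5 (11.1%, against 1.67% of 17400 genes), so it remains open for genes such as Gp2. The amylase gene Amy2a1 (1.168), Zg16 (0.966) and Pla2g1b (0.686) were also among these 17. The slope on the stromal sum, which ranged 6.93-fold, had a median of 0.027 (-0.039 to 0.112) over 152 genes, with 4 over 0.5 (2.63%, against 0.925%), which argues against stromal RNA for most, although Mgp, the 1 stromal gene to compare with, had a slope of only 0.545. A difference between the tissues is still open and was not tested apart from the sort.

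Of 31 maturation and migration genes 19 were higher in liver and 21 in pancreas than in duodenum, but the list tests did not pass with an estimated correlation (adjusted p = 0.0708 and 0.0743). A lower share of DCs there is argued against, since the highest log2 difference of Xcr1, Clec9a, Irf8 and Batf3 against duodenum was 0.288, and with 2 SE added 0.614 in liver and 0.37 in pancreas, below the list medians of 1.37 and 1.45. That holds only if these genes do not themselves change with maturation, which was not tested. Scaling is argued against too, since at least 17 of 31 members were higher in both comparisons under 3 other scalings. Stress during digestion and tissue cannot be told apart, because the lowest immediate-early and heat-shock sum of a duodenum library was 1.58 times the highest of the other tissues, so no libraries match, and the mitochondrial share was higher there too (at least 1.33% against at most 1.24%). A state of the cells that differs between tissues may account for the pattern and stays untested.

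Other groupings of the libraries were fitted in the same way, and the real one gave the most calls each time. That argues against chance only as far as 35 splits or 30 groupings can. The other groupings mix tissues, which widens the spread within their groups, so the size of the gap does not measure chance. For liver versus duodenum 1 of 35 splits, the real one, gave as many genes (3265, against at most 1 in the others), and likewise for pancreas versus duodenum (3437 against 0) and liver versus pancreas (494 against 1). For tissue-specific genes it was 1 of 30 groupings (2470 against at most 127). For list tests 1 of 30 groupings gave as many (51 against at most 44, with a median of 27), so other groupings gave most of the full count.

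Duodenum 2 stood apart in 7 list sums. It was lower for TGF-beta and regulatory genes (810.9 CPM against 1025 to 1064), AHR targets (456.7 against 680.3 to 704.9), B cell genes (171.4 against 239.8 to 252.6), macrophage genes (215.2 against 317.8 to 339.9) and plasmacytoid DC genes (141.3 against 208.3 to 218.9). It was higher for islet genes (7.968 against 6.041 to 6.143) and for NK cell and ILC genes (22.55 against 15.13 to 15.93). Lower sums were not particular to the flagged lists. The cDC1 identity sum was 5414 CPM against 7661 to 8566, and the MHC class II sum 39110 against 55920 to 61190. Ribosomal and repeat features took 15.6% of the counts of duodenum 2 against 9.55 to 12.4%, and its TMM factor was 1.089 against 0.8874 to 0.9241. Whether this composition lowered the sums was not tested. The same library was lower for Ptprc (360.6 CPM), Lgmn (13.32), Il15ra (1.759), Axl (2.311), Dhrs3 (91.93) and Pdlim1 (8.002), and held 0.1006 CPM of Mup22 against 0 in the others. Erythroid genes summed to 130.4 CPM in duodenum 3 against 2.236 to 3.138, and Klra4 was at 1.108 CPM there, while Cpm was at 18.43 CPM in duodenum 1 and Itgal at 6.371 CPM in duodenum 4.

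Maturation genes summed to 2006 CPM in liver 1 against 2706 to 2800, with Ccl5 at 52.39 CPM, Serpina1e at 26.04 CPM and Smad3 at 5.692 CPM in that library. Liver 3 held 59.91 CPM of Cyp8b1 and 0.4179 CPM of Il1r2, and liver 4 held 3.423 CPM of Itgam, 100.5 CPM of Dhrs3 and 0.4802 CPM each of Amy2a2, Amy2a3 and Amy2a4. Pancreas 3 was higher for Ccl5 (611.4 CPM), Cd63 (109.1), Itgal (104.8) and Dhrs3 (324.4) and held 0.02501 CPM of Mup22 against 0 in the others. Pancreas 4 was higher for Ccr9 (19.35 CPM) and Ctla2b (21.42), pancreas 2 lower for Fosb (6.373 CPM), and pancreas 1 lower for Ins2 (4.454 CPM).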

How the results depend on the processing

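The tests without the 3 libraries with immunoglobulin reads, without duodenum 2 and pancreas 1, without antigen receptor and acinar genes and without ribosomal and repeat features were chosen only after the result was seen. No named gene, list test or distance reversed, and 0 genes were called in opposite directions under any alternative run. The larger side of the calls did change: the share higher in liver than in duodenum rose from 46% to 63.5% with library totals, 63.3% with limma on TPM plus 1 and 52.8% at an absolute log2 difference of at least 1, that higher in pancreas than in duodenum from 48.9% to 56.8%, 54% and 55.6%, and to 51.9% without duodenum 3 and 50.9% without pancreas 2, and that higher in liver than in pancreas from 38.5% to 52.2% and 57.7% with the first 2. Of 200 calls of named genes 153 passed under every alternative in which the gene was tested, the stricter thresholds included, 28 were lost when some single library was left out and 33 without the 3 libraries. Of 52 comparisons of named genes that did not pass, 23 passed under some alternative. The distance stayed between -14.08 and -36.77 on the log2 CPM scale, with p = 0.0286 each (exact permutation test). Where a count moved, the cause was not tested, apart from stricter thresholds, which call fewer genes by construction. Settings that leave out libraries also lose power, most of all without the 3 libraries, so calls lost there need not stem from the libraries left out.

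Liver versus duodenum (3265) gave 2069 genes without the 3 libraries, 4913 without duodenum 2 and pancreas 1, 5050 with DESeq2, 1813 at an absolute log2 difference of at least 1 and 1617 at an adjusted p under 0.01. Pancreas versus duodenum (3437) gave 1712 without the 3 libraries, 2068 at the log2 limit and 1827 at 0.01. Liver versus pancreas (494) gave 820 with library totals, 931 with a filter at 1 CPM, 177 without the 3 libraries, 753 with voom sample weights, 971, 932 and 964 with limma on TPM plus 1, 0.1 and 0.5, 1153 with DESeq2 and 248 at 0.01. Tissue-specific genes (2470) gave 1228 without the 3 libraries and 4106 with DESeq2. In the same order, those higher in liver gave 30 and 155, lower in liver 19 and 255, higher in duodenum 642 and 1953, higher in pancreas 70 and 330 and lower in pancreas 57 and 231, and those lower in duodenum gave 410 without the 3 libraries. Without duodenum 2 and pancreas 1, genes lower in liver were 180 and higher in duodenum 1851. List tests (51) gave 11 with an estimated correlation and 87 with fry for changes either way.

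Leaving out 1 library gave 2397 (duodenum 1) to 4807 (duodenum 2) genes for liver versus duodenum, 2596 (duodenum 4) to 4716 (duodenum 2) for pancreas versus duodenum and 343 (liver 2) to 749 (duodenum 2) for liver versus pancreas. Tissue-specific genes ran from 1891 (duodenum 1) to 3788 (duodenum 2), higher in liver 52 to 100, lower in liver 57 to 175, higher in duodenum 765 to 2163, lower in duodenum 661 to 946, higher in pancreas 127 to 229, lower in pancreas 59 to 175, list tests 42 to 54 and the distance -25.46 to -21.12.

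With a replicate block the counts were 2931, 3125 and 436 for the 3 comparisons and 2269 tissue-specific genes, 49 list tests passed and the distance was -23.71. The replicate numbers gave no strong pairing of the libraries, since 0 of 12 pairs with 1 number correlated above 0.1 across genes (r from -0.041 to 0.092). In 4 of the 12 a library correlated more with its own number than with any other. These included replicate 3 in each comparison (r = 0.062, 0.092 and 0.061), so a weak link there is not excluded. With 4 libraries per tissue, simulated 2-fold changes were recovered in 35% to 40% of genes, so calls of that size are incomplete. Those genes had a mean of at least 1 CPM, and rarer genes were not simulated with a change.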

Other observations

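The test without liver 2 and pancreas 3 and 4, the 3 libraries with immunoglobulin reads, was chosen only after the result was seen, and it ended the calls below of Klra4 in liver versus duodenum, of Pdia3, Scd2, Srebf1, Pacsin1, Adgre1 and Il7r in pancreas versus duodenum and of Hk2 and Fcgr2b in liver versus pancreas. Some genes of MHC class I presentation were higher in liver and pancreas than in duodenum, such as Nlrc5, a transactivator of MHC class I genes, at 179 ± 10 CPM in liver, 43.6 ± 6.16 in duodenum and 181 ± 50.8 in pancreas (SD, n = 4 each). Of 21 members 8 were higher in liver and 1, the chaperone gene Calr (-0.68 ± 0.15, SE), was lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.00235, and adjusted p = 0.571 with an estimated correlation). In pancreas 7 were higher and 2, Calr (-0.91 ± 0.15) and the chaperone gene Pdia3 (-0.60 ± 0.15, until any of 5 single libraries was left out), were lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.389). Between liver and pancreas 0 of the 21 were called (0 adjusted over the list alone, camera adjusted p = 0.00436, and adjusted p = 0.581 with an estimated correlation). Genes of LXR and lipid handling were higher than in duodenum for 5 of 20 members in liver and 6 in pancreas, led by the sterol exporter Abcg1 (3.08 ± 0.17 and 2.66 ± 0.16), with 0 lower in liver and 2, Scd2 and, until any of 6 single libraries was left out, Srebf1, lower in pancreas. Those counts were 6 and 3 in liver and 9 and 3 in pancreas adjusted over the list alone (camera adjusted p = 0.00104 and 0.00764, and adjusted p = 0.262 and 0.392 with an estimated correlation). Apoe alone was called between liver and pancreas, higher in liver (2 and 1 adjusted over the list alone, camera adjusted p = 0.527). Glycolysis and hypoxia genes were lower in liver than in duodenum for 4 of 23 members, such as Gapdh (-0.97 ± 0.18), and lower in pancreas for 5, such as Hk2 (-1.41 ± 0.17), with 0 and 2 higher. Adjusted over the list alone 12 and 8 were lower and 0 and 2 higher (camera adjusted p = 0.000488 and 0.0155, and adjusted p = 0.331 and 0.556 with an estimated correlation). Hk2 alone was called between liver and pancreas, higher in liver by 0.86 ± 0.17, until any of 5 single libraries was left out (1 and 4 adjusted over the list alone, camera adjusted p = 0.242). Among 8 AHR targets Asb2 was lower than in duodenum in liver (-2.13 ± 0.21) and in pancreas (-3.16 ± 0.22), and 3 members were lower and 1 higher in each (3 and 1, and 4 and 1, adjusted over the list alone, camera adjusted p = 0.00235 and 0.00329, and adjusted p = 0.118 and 0.124 with an estimated correlation). Asb2 alone was higher in liver than in pancreas, until any of 4 single libraries was left out (1 adjusted over the list alone, camera adjusted p = 0.816).

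Among 26 inflammatory cytokine and chemokine genes Cxcl2, which attracts neutrophils, was at 0.14 ± 0.08 CPM in liver, 7.26 ± 0.87 in duodenum and 0.29 ± 0.29 in pancreas (SD, n = 4 each). Against duodenum 5 were higher and 6 lower in liver and 4 and 4 in pancreas, and 3 were lower in liver than in pancreas (7 and 7, 5 and 5, and 2 higher and 4 lower adjusted over the list alone), with no list test passed (camera adjusted p = 0.908, 0.527 and 0.135). Of 24 pattern recognition genes 4 were higher and 2 lower in liver, and 4 higher and 1 lower in pancreas, with the receptor gene Tlr4 higher in both (2.34 ± 0.38 and 3.26 ± 0.39), while 2 were higher and 2 lower in liver than in pancreas (6 and 3, 4 and 2, and 3 and 2 adjusted over the list alone, camera adjusted p = 0.172, 0.149 and 0.743). Of 29 TGF-beta and regulatory genes 4 were higher and 4 lower in liver than in duodenum, 4 higher and 5 lower in pancreas, and 3 higher and 3 lower in liver than in pancreas (4 and 5, 6 and 8, and 4 and 3 adjusted over the list alone, camera adjusted p = 0.688, 0.989 and 0.394). Smad3, a signal carrier of that pathway, was at 3.90 ± 1.19, 1.62 ± 0.26 and 11.1 ± 2.26 CPM in liver, duodenum and pancreas. The median, the mean and the test differed in sign for the TGF-beta list in each comparison, for the cDC1, MHC class I, inflammatory and cell cycle lists in pancreas versus duodenum, for the MHC class II, LXR, AHR, NK cell, macrophage and monocyte lists in liver versus pancreas, and for the NK cell and stroma lists in liver versus duodenum.

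Lists for other cell types, most of which the gate excludes, gave further values. Plasmacytoid DC genes were lower than in duodenum for 4 of 13 members in liver and in pancreas, such as Atp1b1 (-2.32 ± 0.49 and -2.71 ± 0.49), with 1 higher in each, Cacna1e in liver and, until any of 5 single libraries was left out, Pacsin1 in pancreas (4 and 1, and 6 and 1, adjusted over the list alone, camera adjusted p = 0.00086 and 3.09e-05, and adjusted p = 0.262 and 0.176 with an estimated correlation). Between liver and pancreas 2 were higher in liver, with Cacna1e at 1.55 ± 0.17 (3 and 3 adjusted over the list alone, camera adjusted p = 0.128). T cell genes were lower for 5 of 21 members in liver and 4 in pancreas, such as Ctla4 (-3.80 ± 0.49 and -3.05 ± 0.47), and 0 were called between liver and pancreas. Adjusted over the list alone, 5 were lower and 1 higher in liver, 5 lower in pancreas and 0 called between them (camera adjusted p = 0.00297, 0.00214 and 0.788, and adjusted p = 0.104 and 0.102 with an estimated correlation for the first comparisons). Macrophage and Kupffer cell genes were higher for 3 and lower for 2 of 21 members in liver and higher for 4 and lower for 1 in pancreas, with Adgre1, a macrophage marker, lower in both (-2.27 ± 0.33 and -1.44 ± 0.32). Those counts were 5 and 2, and 4 and 2, adjusted over the list alone (camera adjusted p = 0.0117 and 0.0443, and adjusted p = 0.101 and 0.165 with an estimated correlation). Timd4, an apoptotic cell receptor, was the 1 member called between liver and pancreas, lower in liver until any of 4 single libraries was left out (2 and 2 adjusted over the list alone, camera adjusted p = 0.76). Of 14 monocyte genes 2 were higher and 1 lower in liver than in duodenum, 4 higher and 3 lower in pancreas, and 2 higher and 2 lower in liver than in pancreas (5 and 1, 4 and 4, and 4 and 3 adjusted over the list alone, camera adjusted p = 0.261, 0.527 and 0.788). Of 15 neutrophil genes Il1r2, a decoy receptor, was lower in liver and pancreas than in duodenum (-4.70 ± 0.50 and -3.48 ± 0.47), with 2, 1 and 0 members called in the 3 comparisons, each lower (3, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0108, 0.139 and 0.14, and adjusted p = 0.312 with an estimated correlation for liver versus duodenum). Of 18 genes of NK cells and ILCs Klra4 was lower in liver, until any of 5 single libraries was left out, and in pancreas, where Il7r was higher, and 0 were called between liver and pancreas (1, 2 and 0 adjusted over the list alone, camera adjusted p = 0.986, 0.788 and 0.753). Of 16 B cell genes Fcrla was higher in liver and in pancreas (2.04 ± 0.28 and 2.83 ± 0.28) and Cd79b lower in liver, with 1 higher and 1 lower, 2 and 1, and 0 and 0 members called (2 and 1, 2 and 1, and 1 and 1 adjusted over the list alone, camera adjusted p = 0.527, 0.779 and 0.0953).

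Some islet genes were higher in pancreas, such as the insulin gene Ins2 at 8.08 ± 2.43 CPM there, 0.12 ± 0.05 in liver and 0.11 ± 0.08 in duodenum (SD, n = 4 each). Of 17 members 0 were called between liver and duodenum, and 3 were higher in pancreas than in each other tissue (0, 4 and 5 adjusted over the list alone, camera adjusted p = 0.604, 0.00234 and 0.000203, and adjusted p = 0.102 and 0.0614 with an estimated correlation for the pancreas comparisons). Intestinal epithelium genes went both ways, since Epcam, an adhesion gene that DCs also express, was lower in liver than in duodenum (-2.22 ± 0.26), while Zg16 was at 66.4 ± 39.9 CPM in pancreas and at 1.17 CPM or less in each library of the other tissues. The slope of Zg16 on the acinar sum over the pancreas libraries was 0.966, so acinar RNA remains open as its source there. Of the 30 epithelium genes 1 was higher and 3 lower in liver than in duodenum, 3 higher and 3 lower in pancreas, and 1 higher and 2 lower in liver than in pancreas (1 and 3, 4 and 4, and 2 and 9 adjusted over the list alone). The camera adjusted p was 0.0263, 0.604 and 3.57e-05, and adjusted p = 0.165 for the first and adjusted p = 0.027 for the last with an estimated correlation. Of 17 endothelial genes Fcgr2b, an inhibitory Fc receptor that DCs also express, was at 51.2 ± 11.6, 5.84 ± 2.37 and 145 ± 3.45 CPM in liver, duodenum and pancreas, with 1 higher and 1 lower, 2 and 3, and 1 and 1 members called (1 and 1, 2 and 5, and 4 and 2 adjusted over the list alone, camera adjusted p = 0.685, 0.475 and 0.12). Of 16 stromal genes 0 were called between liver and duodenum, 3 were higher in pancreas than in duodenum, and 1, Mgp, was lower in liver than in pancreas until any of 5 single libraries was left out (0, 6 and 6 adjusted over the list alone). Its camera adjusted p was 0.966, 0.0368 and 0.00116, and adjusted p = 0.398 and 0.182 with an estimated correlation for the pancreas comparisons. The stromal sum was 68.93 and 71.73 CPM in pancreas 3 and 4 but 13.7 and 10.35 in pancreas 1 and 2, near the 9.862 to 15.51 of liver and 9.947 to 15.66 of duodenum, and without liver 2 and pancreas 3 and 4 Mgp was called in neither pancreas comparison. Of 7 erythroid genes 0 were called in any comparison (4 lower in liver than in duodenum and 0 otherwise adjusted over the list alone, camera adjusted p = 0.356, 0.527 and 0.554).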
